A study of Arabidopsis thaliana with 12 samples.

How the data were processed

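RNA from whole seedlings was measured on one-colour Agilent arrays, 3 for each of 4 groups: the wild type and the anac060 mutant of Arabidopsis thaliana, each on 6% sorbitol and on 6% glucose. Per the labels, seeds were stratified for 3 days and seedlings then grew for 4 days at 22 °C in constant light on agar. Per the file headers, the authors scanned the arrays and read the spots with Agilent Feature Extraction 10.7.1.1. The deposited scanner files hold the linear intensity of each spot on the array, background subtracted and detrended within the array by that software but not scaled between arrays, together with raw intensity, local background and marks of spot quality. A second deposited file, the value table, gives log2 values for all arrays, and its processing is not given in the sources used here. It was checked against the scanner files: its values followed the rank of the median intensity minus the local background (Spearman of at least 0.9995 within each array), every array had the same median of 7.82, and the slope against the log2 signal was 0.954 to 0.985. It was therefore read as quantile normalized log2 signal, centred on no sample, with higher values for more transcript, and it was used only as an alternative.

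Each array held 45220 spots, of which 43803 were not controls and 1417 were controls. The 75th percentile of the processed signal ran from 978 to 1791 and the share of spots well above background from 68.2% to 73.3%. No spot was saturated, 3 to 11 spots per array were marked as outliers and set to missing, and 7 values were missing among the tested genes. The spike-in slopes ran from 0.951 to 1.01 and the median coefficient of variation of repeated spots from 4.04% to 6.15%. Of 43603 probes, 36495 were paired with 1 locus, through a RefSeq accession (34358), a locus code (1880) or a locus code outside the reference table (257), and 7108 were paired with none. Gene names came from the array files and from a RefSeq gene table of assembly TAIR10.1, whose coordinates are not printed, since the array files name an older build. The neighbourhood of genes along the chromosomes was taken from that table. The 26587 loci, 7624 of them with more than 1 probe, were each represented by the probe with the highest mean signal. Among called genes, 84.0% to 96.7% of the other probes of a gene, depending on the comparison, had the same sign of change.

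The processed signal was put on the log2 scale and the 75th percentile of each array subtracted. Genes well above background on at least 3 of 12 arrays were kept, which left 20821 genes and put 5766 aside as dim. limma 3.58.1 in R 4.3.3 was fitted to the 4 groups with empirical Bayes moderation (8 residual and 2.08 prior degrees of freedom), and 5 comparisons were taken: the effect of glucose in each genotype, the effect of genotype on each sugar, and the interaction. P values were adjusted by Benjamini-Hochberg within each comparison, and genes with an adjusted p under 0.05 were called. Tests were two-sided. For a probe not well above background on any array of a group, the lower bound of the fold took the detection limit of each array where the probe's value was lower. That limit was the lowest value among all probes well above background on the array. It belongs to the array and not to the probe, so the bound is approximate. Tables were handled with the data.table package (1.17.8), Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.

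The gene lists, the named genes, the tests and the alternatives were chosen before the data were examined, except where stated. A total of 365 list members were fixed in 18 lists, and 7 members were dropped because their names did not pair. The 17 lists with at least 3 tested members were tested in the 5 comparisons by camera in limma with a preset correlation between genes of 0.01, and the 85 p values were adjusted together. With the preset correlation 33 of the 85 tests passed, with a correlation estimated from the data none did, and with fry, which asks whether the genes of a list move on balance one way, 46 did. Fry lost 3 of the 33 calls and gained 16. Below, a list is called by camera with the preset correlation unless fry is named. Named genes were, per comparison, the 10 largest rises and 10 largest falls among called genes that had a symbol, were well above background on all arrays of at least 1 group, and, outside the interaction, had ranges of the 3 arrays that did not overlap, as 1 in 10 random splits would give. Up to 4 members of each list with the smallest adjusted p and 15 fixed genes (ANAC060, ABI3, ABI4, ABI5, HXK1, RD29B, RAB18, EM6, TT4, PAP1, GPT2, APL3, ASN1, LHCB1.1 and RBCS1A) were added. Some list members were left out for room, those with the larger change being kept first.

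The alternatives tried were normexp background correction with an offset of 50, quantile normalization, median centring, the value table, no filter on dim probes, a filter of 6 arrays, outlier spots kept, the mean of a gene's probes, the most detected probe, limma with trend and robust moderation, only the groups compared, slide or replicate number as a block, a stricter adjusted p of 0.01, calls of at least 2-fold, and leaving out each array in turn. Fits on slide 1 or slide 3 alone were added after seeing the data. Slides were read from the barcodes in the array files. When a model with slide as a term was fitted, the adjusted test of a slide difference called 0 genes between slides 1 and 2 (1085 at an unadjusted p under 0.05), 3 between slides 2 and 3 (1689) and 0 between slides 1 and 3 (884). The step from slide 1 to 2 rested on WT glucose array 1 against arrays 2 and 3. That from slide 2 to 3 rested on anac060 sorbitol array 3 against arrays 1 and 2. Neither step can be told from the deviation of its lone array, so few calls do not exclude a slide effect. The procedure was tested on simulated data: for the effect of glucose in the wild type, 200 of 20821 genes were changed by a known amount in data with no other difference between the groups, and 40% of them were called at a log2 change of 0.5, 80% at 1, 94% at 2 and 100% at 3, with 12 false calls over all sizes. The wild type effect alone was simulated. The real comparison called 10643 genes, and the adjustment is stricter where only 200 genes change. These shares and false calls therefore do not give the sensitivity or error of the real comparison. Unnamed probes were fitted in the same way but were not used in the comparisons, and probes without a locus are not analysed further here.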

Results

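Transcript levels were measured in seedlings of Arabidopsis thaliana with 12 one-colour Agilent oligonucleotide arrays. The wild type and the anac060 mutant were each grown on agar with 6% glucose or with 6% sorbitol, and 3 arrays were made for each of the 4 groups. Glucose acts on plants both as a nutrient and as a signal, and at a high level it holds back greening and growth of young seedlings. Sorbitol served as the control of like osmotic strength. The ANAC060 gene encodes a transcription factor of the NAC family, which is known from earlier work to dampen the responses of seedlings to sugar and to abscisic acid (ABA). Between 68.2% and 73.3% of the non-control spots of an array were well above background, no spot was saturated, and 20821 genes with a signal on at least 3 arrays were tested. Correlations between arrays of the same group ran from 0.984 to 0.996 and those between groups from 0.868 to 0.987 (Pearson r across genes, which are not independent replicates). Nothing in the labels says that the 3 arrays of a group came from separate cultures, so every p measures the spread between these samples, which may be technical. The number of arrays limits the precision.

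The arrays lay on 3 slides of 4 arrays. Slide 1 held the 3 arrays of the wild type on sorbitol and array 1 of the wild type on glucose. Slide 2 held arrays 2 and 3 of the wild type on glucose and arrays 1 and 2 of anac060 on sorbitol. Slide 3 held array 3 of anac060 on sorbitol and the 3 arrays of anac060 on glucose. Each effect of glucose could therefore also be taken within 1 slide, whereas no slide held both genotypes on the same sugar. Genotypes were joined across slides only through a chain of shared groups, and the values with slide as a block are given beside each comparison.

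The probe of ANAC060 (AT3G44290, chromosome 3, 15983903 to 15983962 by the coordinates of the array file) was read first in every array. In the wild type its log2 level relative to the 75th percentile was -2.05 ± 0.22 on sorbitol and -2.02 ± 0.29 on glucose (mean and SD of 3 arrays). The single arrays read -1.96, -1.90 and -2.30 on sorbitol and -1.70, -2.13 and -2.25 on glucose, all well above background. In anac060 it was -6.85 ± 0.16 on sorbitol, where no array was well above background, and -6.04 ± 0.32 on glucose, where 1 of 3 arrays was. Where this 1 probe lies relative to the mutation could not be placed, so a low signal does not show that the whole transcript is lost. The ANAC060 signal was lower in all 6 mutant arrays than in all 6 wild type arrays. On sorbitol it was at least 18.5-fold lower in anac060 (log2 difference -4.80 ± 0.19 (SE), adjusted p = 6.4e-07), and on glucose the log2 difference was -4.02 ± 0.19 (adjusted p = 5.0e-07). An "at least" fold sets each array of the undetected group at the detection limit of that array, or at its own value if higher. It is an approximate bound, and the log2 difference beside it is the fitted value. Glucose left ANAC060 without a called change in the wild type (0.03 ± 0.19, adjusted p = 0.92). In anac060 the residual signal was 0.81 ± 0.19 higher on glucose (adjusted p = 0.0028), but 5 of the 6 arrays were not well above background, so no fold is given.

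**Figure D1:**
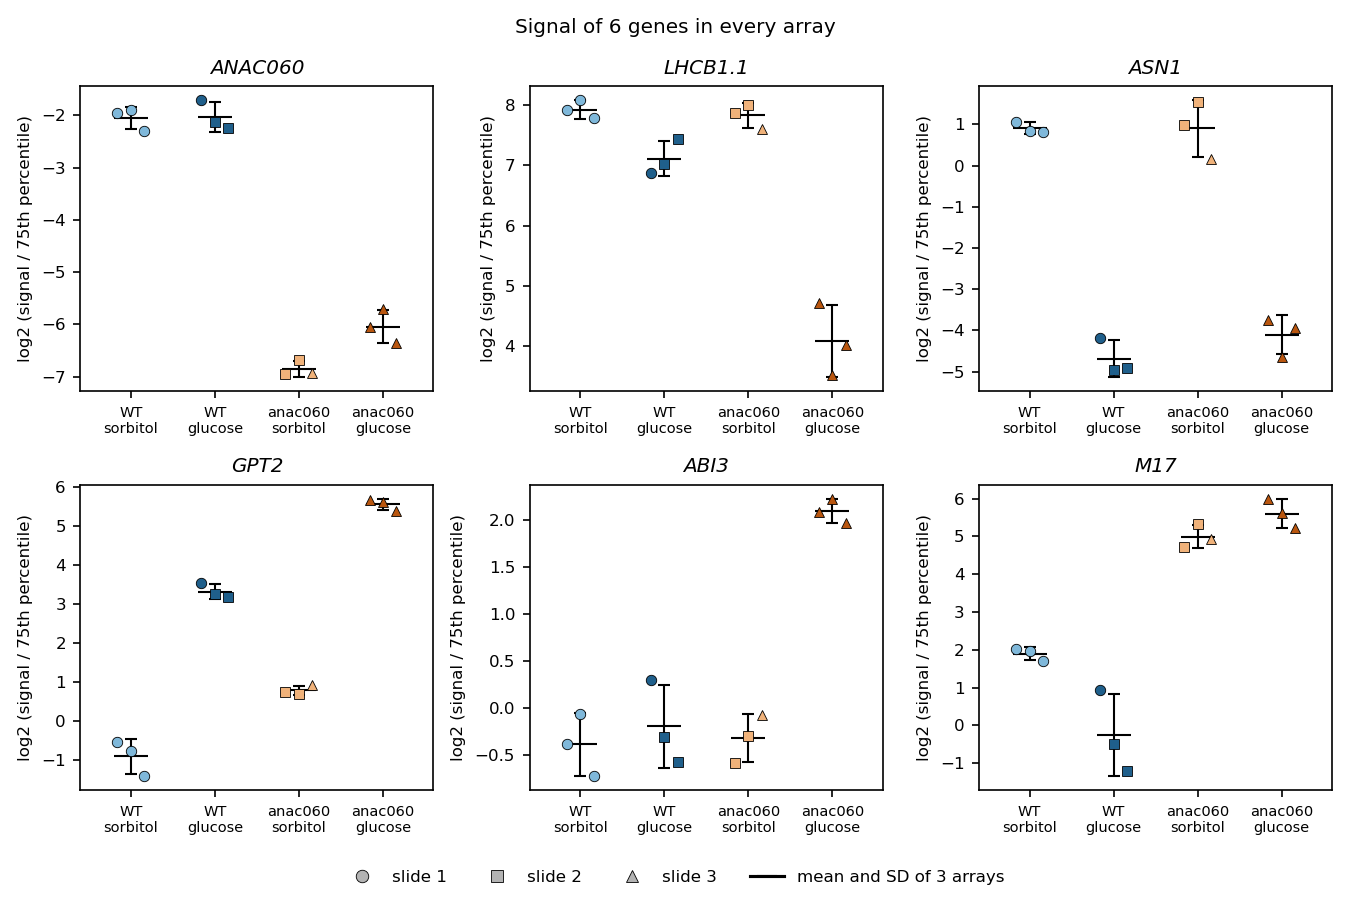
Log2 signal relative to the 75th percentile of each array for ANAC060, LHCB1.1, ASN1, GPT2, ABI3 and M17 in the 4 groups; points are single arrays, shapes give the slide, and bars are the mean and SD of 3 arrays. ANAC060 lay between -2.30 and -1.70 in the wild type arrays and between -6.95 and -5.71 in the anac060 arrays.

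The first comparison asked which transcripts glucose changed in the wild type. By list tests with a preset correlation, photosynthesis and sugar starvation genes fell, and cell cycle genes and most anthocyanin genes rose, but none of these 4 calls held with an estimated correlation (adjusted p from 0.507 to 0.636). MGDC, which encodes a galactolipid synthase used when phosphate is short, was at least 16.7-fold higher on glucose (5.23 ± 0.47, adjusted p = 3.4e-05). GPT2, the glucose 6-phosphate transporter of plastids, rose by 4.23 ± 0.20 (adjusted p = 1.8e-06). ASN1, the asparagine synthetase gene that sugar represses, fell by 5.59 ± 0.35 on the log2 scale (adjusted p = 6.4e-06). In all, 10643 genes were called in limma, 6427 higher and 4216 lower on glucose. Of these, 1947 changed at least 2-fold, 753 higher and 1194 lower.

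Further rises were those of the lipid transfer protein gene LTP4 (4.92, detected on 2 of 3 sorbitol arrays), the acyltransferase gene GLC (4.57, at least 9.06-fold), the phosphate sensing gene SPX3 (4.43, at least 4.36-fold) and PEPC1 (4.25, at least 16.7-fold), which encodes a phosphatase that frees phosphate from lipid head groups. BHLH100, a regulator of iron uptake, rose by 4.14 ± 1.13 (adjusted p = 0.012) with 2 of 3 sorbitol arrays above background. It rose by 2.48 without WT sorbitol array 2, and the call was lost with slide as a block (4.51, adjusted p = 0.0767). BGLU28 (4.05) and LSU1 (3.72), both known from sulfur shortage, and the amylase gene BAM5 (4.01, at least 9.73-fold) completed the 10 largest rises. After ASN1 the largest falls were those of JRG21 (-4.13, at least 9.77-fold), the glutamate receptor-like gene GLR2.3 (-4.07, at least 4.88-fold), HR4 (-3.89), the sugar transporter gene SWEET3 (-3.62, at least 6.52-fold) and the small heat shock gene HSP17.6A (-3.58). BCAT-2 of branched-chain amino acid breakdown (-3.56), BT5 (-3.35), CYP71A22 (-3.35, at least 3.08-fold) and the senescence regulator NAP (-3.30) followed.

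Photosynthesis genes fell together: all 55 measured members were lower on glucose, among them LHCA3 (-1.27), LHCB2.1 (-1.36) and PSAG (-1.22), with a list median of -1.09 (camera with the preset correlation of 0.01, adjusted p = 5.5e-22; adjusted p = 0.530 with an estimated correlation). LHCB1.1 fell by 0.81 on the log2 scale (adjusted p = 0.026). This call was lost under quantile normalization (-0.20), in the authors' value table (-0.21) and with slide as a block (-1.06, adjusted p = 0.0597). It was also lost without WT sorbitol array 1 (adjusted p = 0.0579) or 2 (0.0818) or WT glucose array 1 (0.0890) or 2 (0.0725). RBCS1A, of the small subunit of Rubisco, had a log2 difference of -0.43 (adjusted p = 0.013; its other probes from -0.90 to -0.48). Its sign turned under quantile normalization (0.15) and in the value table (0.05), and without WT sorbitol array 2 its adjusted p was 0.0509. Of 18 chlorophyll synthesis genes 11 fell and 1 rose, with HEMA1 at -1.37, CAO at -0.92 and GUN5 at -0.91 (median -0.48, camera adjusted p = 5.0e-04; adjusted p = 0.650 with an estimated correlation). Probes of close paralogs such as LHCB1 and LHCB2 genes may share signal, as may those of the SESA, CYP71A12/CYP71A13 and SAUR genes named further on.

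Of 20 sugar starvation induced genes 17 fell and none rose, with TPS11 at -2.14, DIN10 at -1.90 and MIOX2 at -1.69 beside ASN1 (median -1.17, camera adjusted p = 1.2e-10; adjusted p = 0.507 with an estimated correlation). Anthocyanin and flavonoid genes rose: 23 of 31 were higher and 4 lower (24 and 4 adjusted over the list alone), with LDOX at 1.87, UF3GT at 1.80, GSTF12 at 1.76 and DFR at 1.62 (median 0.65, camera adjusted p = 1.3e-04; adjusted p = 0.507 with an estimated correlation). Their regulator PAP1 rose by 1.32 ± 0.20 (adjusted p = 4.8e-04). Of 20 cell cycle and DNA replication genes 19 rose and none fell, with HINKEL at 0.97, CYCB1;4 at 0.91 and PCNA1 at 0.81 (median 0.75, camera adjusted p = 2.4e-06; adjusted p = 0.636 with an estimated correlation). Counts adjusted over the list alone equalled those over all genes wherever no second count is given.

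The other lists had no call by camera in the wild type. Fry did call the sugar sensing, transport and starch list (fry adjusted p = 2.8e-05) and the lipid reserve mobilisation list (1.3e-04). It also called the ABA synthesis and catabolism list (0.0064). The values that follow are those of camera. Lipid reserve mobilisation genes numbered 8 higher and 0 lower of 13 (median 0.34, camera adjusted p = 0.0517), with MFP2 of fatty acid breakdown at 1.32 and PKT3 at 0.80 (up to 1.23 by other probes). This list was called under several other choices: normexp (adjusted p = 0.0078), quantile normalization (0.0211), the value table (0.0136), no filter on dim probes (0.0159), the mean (0.0273) or the most detected (0.0239) of a gene's probes and slide as a block (0.41, 0.0471). It was also called without WT sorbitol array 2 (0.0167), WT glucose array 1 (0.0473) or WT glucose array 3 (0.0380). Seed storage and maturation genes numbered 3 higher and 9 lower of 20 (median -0.59, mean -0.32, adjusted p = 0.0665), from SESA1 at 2.45 to M17 at -2.15 (-0.97 and 0.0736 with slide as a block). WT glucose array 1 stood apart in this list, at a mean level of 0.55 relative to wild type sorbitol against -0.61 and -0.89 in arrays 2 and 3; without it the list was called lower (-0.91, adjusted p = 1.8e-04). ABA signalling genes numbered 3 higher and 6 lower of 30 (-0.20, adjusted p = 0.0947; 0.0112 without WT sorbitol array 1). ABA and dehydration induced genes numbered 3 and 3 of 25 (2 and 2 over the list alone; -0.07, 0.434), and ABA synthesis and catabolism genes 2 and 4 of 14 (-0.21, 0.0882; 0.0429 without WT glucose array 1). Sugar sensing, transport and starch genes numbered 9 higher and 4 lower of 25 (0.14, 0.355), with APL3 at 1.55 and HXK1 at 0.64. Jasmonate genes numbered 1 and 1 of 16 (0 and 0 over the list alone; -0.17, 0.434) and salicylate and camalexin defence genes 2 and 0 of 11 (-0.15, 0.631). Nitrate genes numbered 4 and 4 of 9 (-0.38, 0.520), and guard cell markers 0 and 1 of 5 (0 and 0 over the list alone; -0.18, 0.528). Root markers numbered 5 and 2 of 20 (4 and 1 over the list alone; 0.23, 0.779). Expansin and wall genes numbered 2 and 4 of 11, with a median of 0.09 against a mean of -0.19 and a camera direction of down (0.520). Neither of 2 membrane-tethered NAC genes was called. Among the fixed genes, ABI4 rose by 0.73 (adjusted p = 0.0054) and EM6 fell by 1.04 (0.011; -0.29 and not called with slide as a block). ABI3 (0.20), ABI5 (-0.04) and RD29B (0.06) were not called. TT4 rose by 0.49 (adjusted p = 0.025), a call lost without WT sorbitol array 1 (0.0857) or 2 (0.0596) or WT glucose array 1 (0.0922). RAB18 fell by 0.76 (adjusted p = 0.045), but the value was -0.22 by another probe and -0.04 with slide as a block. The call was lost under quantile normalization (-0.61), in the value table (-0.49), with no filter on dim probes (0.0630), with only the groups compared (0.113) and with the mean (0.110) or the most detected (0.0794) of its probes, and it was lost without any single array other than WT glucose array 1 (adjusted p from 0.0540 to 0.124).

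Blocking on slide left 7789 genes called, and 7462 of them had also been called without the block, in the same direction. Within slide 1, with 1 glucose array against 3 sorbitol arrays and on the assumption that the lone array varies like the others, 5822 were called, but not PAP1 (1.12, 0.0752), RBCS1A (-0.50, 0.0931), BHLH100 (0.183), EM6 (0.266) or RAB18 (0.851). Only slide 1 held both wild type groups, so the blocked and the within-slide medians were the same: -1.34 for photosynthesis, -0.65 for chlorophyll synthesis, -1.23 for sugar starvation, 0.77 for anthocyanin, 0.80 for the cell cycle and 0.31 for the seed list, whose sign thus turned. Under normexp background correction 49.3% of the called genes were higher on glucose, against 60.4% here.

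The second comparison asked the same of glucose in the anac060 mutant. Genes of the photosynthetic apparatus fell many-fold: LHCB2.3 of the light harvesting antenna had a log2 difference of -6.92 ± 0.33 and the carbonic anhydrase gene CA1 one of -6.72 ± 0.16. XTH6, which encodes a cell wall remodelling enzyme, was at least 89.6-fold lower on glucose (-8.75 ± 0.34, adjusted p = 3.2e-08). BAM5 was at least 33.8-fold higher (5.88 ± 0.24, adjusted p = 4.0e-08) and the seed storage gene SESA1 rose (3.99 ± 0.45, adjusted p = 1.8e-05). In all, 15633 genes were called, 9331 higher and 6302 lower on glucose. Of these, 5905 changed at least 2-fold, 2604 higher and 3301 lower.

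Other large rises were those of CYP722A1 (5.86, at least 23.63-fold), BGLU28 (5.86, detected on 2 of 3 sorbitol arrays), CORI3 (5.72; 3.81 and 6.27 by its other probes), which encodes a cystine lyase induced by jasmonate, BGLU27 (5.19, at least 12.4-fold), and the lipase gene GLIP1 (5.07, at least 7.93-fold). The size of the last 2 rested on anac060 glucose array 1, without which the bounds were 5.54-fold and 2.54-fold. ATSDI1 of sulfur shortage (4.98), GPT2 (4.77), the senescence marker SAG13 (4.66, at least 6.94-fold, or 4.12-fold without the same array) and MGDC (4.59, at least 6.15-fold) followed. Other large falls were those of the aldolase gene FBA5 (-7.44), SNG1 of sinapoylmalate synthesis (-6.83; -3.99 by its other probe), the plastid phosphoenolpyruvate transporter gene PPT2 (-6.64, at least 20.6-fold) and the auxin-induced gene SAUR63 (-6.45, at least 41.3-fold). CP12-2, a regulator of the Calvin cycle, stood at -6.43, CIPK20 at -6.33 (at least 22.0-fold) and NEET at -6.27. ASN1 fell by 5.01 on the log2 scale.

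All 55 photosynthesis genes fell, with LHCB2.1 at -5.33, LHCB4.2 at -4.69 and PETE1 at -4.60 (median -3.84, camera adjusted p = 6.6e-28; adjusted p = 0.507 with an estimated correlation). LHCB1.1 was at -3.75 ± 0.26 and RBCS1A at -0.94 ± 0.12, the smallest fall among its 13 probes (the others from -2.48 to -1.06). Of 18 chlorophyll synthesis genes 17 fell and none rose, with GUN5 at -3.94 and CAO at -2.87 (median -1.94, adjusted p = 8.6e-10; adjusted p = 0.507 with an estimated correlation). Of 20 sugar starvation induced genes 16 fell and 2 rose, with DIN4 at -2.62 and TPS11 at -2.35 (median -1.83, adjusted p = 9.2e-06; adjusted p = 0.507 with an estimated correlation). Of 20 cell cycle genes 15 rose and none fell, with CDKB1;1 at 1.63 and MCM2 at 1.52 (median 0.66, adjusted p = 0.0084; adjusted p = 0.742 with an estimated correlation). Of 13 lipid reserve mobilisation genes 8 rose and none fell, with MFP2 at 1.78 and PCK1 at 1.29 (median 0.62, adjusted p = 0.0237; adjusted p = 0.636 with an estimated correlation). All 5 guard cell markers fell, with MYB60 at -2.94 and the potassium channel gene KAT1 at -2.05, the latter above background on 1 of 3 glucose arrays (median -0.91, adjusted p = 0.0175; adjusted p = 0.636 with an estimated correlation). Root markers fell, 12 lower and 3 higher of 20, with the xylem channel gene SKOR at -2.31 and the endodermal genes CASP5 at -2.25 and CASP1 at -1.67 (median -1.15, adjusted p = 0.0487; adjusted p = 0.673 with an estimated correlation). The root call was lost without WT glucose array 3 (adjusted p = 0.0509), anac060 sorbitol array 1 (0.0518) or 3 (0.0817) or anac060 glucose array 1 (0.0831). It was also lost under median centring (0.0539) and with slide as a block (0.0508). With only the groups compared it was lost too (0.0603), and over all settings with the preset correlation its adjusted p ran from 0.0141 to 0.0831.

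Seed storage and maturation genes numbered 14 higher and 3 lower of 20, with CRB at 3.02, OLEO2 at 2.56 and RAB28 at 2.23, but the list was not called (median 1.26, adjusted p = 0.177; 0.0382 without WT glucose array 1, 0.0248 with only the groups compared and 0.0183 within slide 3, whose 1 sorbitol array was assumed to vary like the glucose arrays). Anthocyanin genes numbered 21 higher and 6 lower (median 0.71, adjusted p = 0.0834; 0.0235 within slide 3, under the same assumption), with MYB113 at 3.73 (at least 4.51-fold) and TT7 at 2.66. Sugar sensing, transport and starch genes numbered 17 and 6 (0.59, 0.177), with the starch synthesis genes APL4 at 3.85, APL3 at 2.77 and GBSS1 at 1.87. The ABA lists went both ways. ABA signalling genes numbered 14 higher and 9 lower (median 0.28 and mean 0.21 against a camera direction of down, 0.975), and ABA and dehydration induced genes 13 and 5 (0.66, 0.442). ABA synthesis and catabolism genes numbered 7 and 5 (median 0.36 and mean 0.12 against a camera direction of down, 0.839). Among the fixed regulator genes, ABI3 rose by 2.42 ± 0.23 (adjusted p = 5.7e-06), ABI4 by 2.28 ± 0.17 (1.0e-06) and ABI5 by 1.56 ± 0.21 (7.4e-05). The ABA signalling genes ABF4 and PYL8 went the other way, at -1.19 and -1.52. NCED5 of ABA synthesis rose by 2.24, ADH1 by 3.09 and RD29B by 1.06. EM6 rose by 0.82 (adjusted p = 0.022), a call lost without anac060 sorbitol array 1 (0.0688) or 2 (0.0543) or anac060 glucose array 1 (0.0527) or 3 (0.0518). RAB18 (0.66, adjusted p = 0.053) was not called here but was under quantile normalization (1.35, 0.0035), in the value table (1.33, 0.0062), under 6 other settings and without WT glucose array 1 or 3. PAP1 rose by 0.74 (adjusted p = 0.0070; 0.0722 with slide as a block), HXK1 by 0.79 and TT4 by 0.71. Jasmonate genes numbered 4 higher and 5 lower (4 and 4 over the list alone; median 0.51 and mean 0.23 against a camera direction of down, 0.828), with PDF1.2 at 2.24 and VSP2 at -2.07. Salicylate and camalexin defence genes numbered 3 and 2 (median -0.01, mean 0.29, camera direction down, 0.822). Expansin and wall genes numbered 3 and 4 (-0.05, 0.355) and nitrate genes 1 and 4 (0 and 4 over the list alone; -0.56, 0.0834), with GLU1 of glutamate synthesis at -3.75. Of the membrane-tethered NAC genes ANAC089 rose by 1.24.

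Blocking on slide left 12896 genes called, 12625 of which were also called in the same direction without the block, and within slide 3, with 3 glucose arrays against 1 sorbitol array and on the same assumption, 8213 were called. Within slide 3 the calls of BGLU27 (5.34, 0.0635), GLIP1 (5.54, 0.120), CASP1 (-1.75, 0.130), CASP5 (-2.34, 0.0607), TT4 (0.61, 0.164) and ANAC060 (0.89) were lost. Blocked and within-slide medians were again equal: -3.60 for photosynthesis, -1.73 for chlorophyll synthesis, -1.61 for sugar starvation, 0.59 for the cell cycle, 0.66 for lipid mobilisation, -0.92 for guard cell markers, -1.29 for root markers and 0.94 for the seed list.

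**Figure D2:**
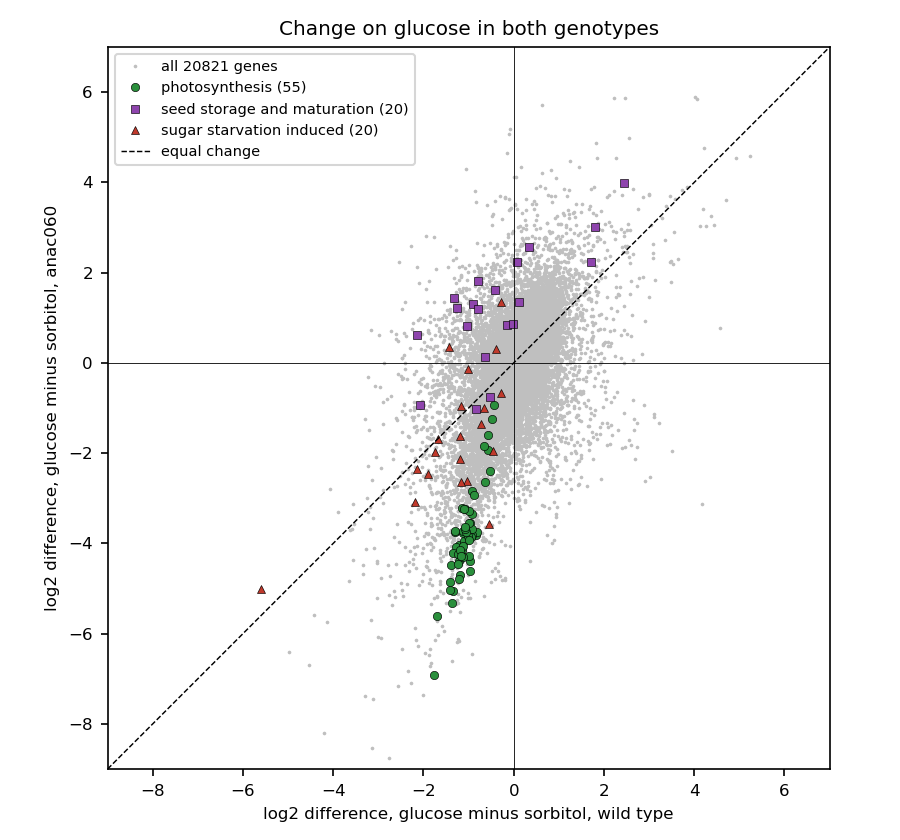
Log2 difference between glucose and sorbitol in the wild type (x axis) and in anac060 (y axis) for 20821 genes, with the photosynthesis, seed storage and sugar starvation lists in colour; the dashed line marks equal change. The photosynthesis genes had a median of -1.09 on the x axis and -3.84 on the y axis.

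Both genotypes shared many of these changes. Across genes the effects of glucose in the wild type and in anac060 had a Pearson r of 0.565 and a Spearman rho of 0.551 (genes are not independent replicates), and r was 0.663 with slide as a block. Both effects were called and upward for 5029 genes, where independence gave 2880, and both downward for 2900, where independence gave 1276. A further 418 genes rose in the wild type and fell in anac060, and 429 did the reverse.

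The third comparison asked how the genotypes differed on glucose. In anac060 the photosynthesis genes were lower and the seed maturation genes higher than in the wild type by list tests with the preset correlation, though not with an estimated one (adjusted p of 0.507 and 0.636). CYP71A13, of camalexin synthesis, was at least 93.3-fold higher in anac060 (8.48 ± 0.45, adjusted p = 8.3e-07) and the seed protein gene M17 was 5.86 ± 0.44 higher (adjusted p = 4.1e-06). The antenna gene LHCB2.3 had a log2 difference of -4.85 ± 0.33 (adjusted p = 2.3e-06). In all, 13932 genes were called, 7136 higher and 6796 lower in anac060. Of these, 4372 differed at least 2-fold, 1443 higher and 2929 lower.

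The other genes most raised in anac060 were the glutathione transferase gene GSTU11 (6.86, above background on 1 of 3 wild type arrays), the defensin gene PDF1.4 (6.52, at least 76.4-fold), and ENODL1 (6.23, at least 46.2-fold). The thioredoxin gene TH8 (6.01), BGLU27 (5.92, at least 12.5-fold), M10 (5.67), the embryo gene PEI1 (5.48, at least 18.9-fold) and CYP71B22 (5.41, at least 8.66-fold) were next. Without anac060 glucose array 1 the bounds were 5.55-fold for BGLU27, 3.92-fold for CYP71B22 and 59.5-fold for CYP71A13. The genes most lowered were GH9B15 (-5.50, at least 16.2-fold, but -3.93 and -1.58 by its other probes), the root growth peptide gene RGF9 (-5.44, above background on 1 of 3 anac060 arrays), MRD1 (-5.37) and SAUR63 (-5.29, at least 18.4-fold). Next came ESP of glucosinolate breakdown (-5.06, 1 of 3 arrays, but -3.36 by another probe), SAUR20 (-4.96, at least 8.68-fold), ckl10 (-4.78), GASA6 (-4.74, but -3.72 by its other probe) and the cellulose synthase-like gene ATCSLB05 (-4.73, at least 17.1-fold).

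All 55 photosynthesis genes were lower in anac060, with PETE1 at -3.58, LHCB4.2 at -3.23, LHCA2 at -3.19 and LHCB1.1 at -3.03 (median -2.69, camera adjusted p = 6.3e-25; adjusted p = 0.507 with an estimated correlation). RBCS1A was at -0.75 (other probes from -1.29 to -0.79; adjusted p = 3.1e-04; -0.47 and 0.0955 with slide as a block). Of 18 chlorophyll synthesis genes 17 were lower and none higher, with PORA at -2.42 (-1.55 by another probe), GUN5 at -2.32 and PORB at -2.29 (median -1.38, adjusted p = 6.8e-08; adjusted p = 0.538 with an estimated correlation). Of 20 seed storage and maturation genes 18 were higher and none lower, with PER1 at 3.89, OLEO2 at 3.70 and RAB28 at 2.77 (median 2.56, adjusted p = 9.2e-06; adjusted p = 0.636 with an estimated correlation). Root markers were lower, 14 of 20 with 2 higher, with SKOR at -2.59, CASP1 at -2.39 and CASP4 at -2.31 (median -1.74, adjusted p = 0.0090; adjusted p = 0.636 with an estimated correlation). Guard cell markers were lower, 4 of 5 (5 of 5 over the list alone), with KAT1 at -2.69 (1 of 3 anac060 arrays), MYB60 at -2.17 and TMM at -1.51 (median -1.51, adjusted p = 0.0164; adjusted p = 0.636 with an estimated correlation), but not with slide as a block (-1.20, adjusted p = 0.0503). Of 13 lipid reserve mobilisation genes 8 were higher, with MFP2 at 0.80 (median 0.32, adjusted p = 0.0240; adjusted p = 0.636 with an estimated correlation), a call lost with slide as a block (0.29, adjusted p = 0.0512).

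Sugar sensing, transport and starch genes were higher, 16 of 25 with 4 lower, with GPT2 at 2.24, APL3 at 1.46 and GBSS1 at 1.44 but the glucose importer gene STP1 at -1.84 and APL1 at -1.68 (median 0.41, adjusted p = 0.0443; adjusted p = 0.530 with an estimated correlation). This call was lost without anac060 sorbitol array 1 (0.0518) or anac060 glucose array 3 (0.0707), with slide as a block (0.36, 0.0631) and under normexp (0.0713), quantile normalization (0.0556) and median centring (0.0539). With only the groups compared it was 0.0606, and over all settings with the preset correlation the adjusted p ran from 0.0255 to 0.0713. The remaining lists were not called by camera. ABA signalling genes numbered 8 higher and 10 lower (median -0.04, mean 0.04, 0.885), ABA and dehydration induced genes 10 and 6 (0.32, 0.434) and ABA synthesis genes 7 and 3 (0.46, 0.354), with NCED5 at 2.42. Anthocyanin genes numbered 14 and 6 (0.31, 0.354), sugar starvation genes 4 and 9 (-0.21, 0.366), and cell cycle genes 7 and 5 (0.04, 0.828). Jasmonate genes numbered 5 and 5 (0.28, 0.998), with PDF1.2 at least 8.62-fold higher and VSP2 at -2.17, and salicylate and camalexin genes 3 and 3 (median -0.04, mean 0.78, 0.883). Expansin genes numbered 1 and 5 (-0.22, 0.242), nitrate genes 1 and 4 (-0.31, 0.199) and the membrane-tethered NAC genes 1 and 1, with ANAC089 at 1.395. ABI3 was 2.29 ± 0.23 higher in anac060, ABI4 1.97 ± 0.17, ABI5 1.88 ± 0.21, EM6 2.12 ± 0.28, RAB18 1.88 ± 0.28 and RD29B 1.27 ± 0.27. PAP1 was at -1.14, TT4 at 0.60 (0.53 and not called with slide as a block) and ASN1 at 0.58 (adjusted p = 0.17, not called). HXK1 was at 0.20 (adjusted p = 0.033), a call lost with slide as a block (0.376) and without WT glucose array 2 (0.0901) or 3 (0.117) or anac060 glucose array 2 (0.0616) or 3 (0.0827), with no filter on dim probes (0.0513) and with only the groups compared (0.0581).

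A model blocked on slide called 7694 genes, 7517 of which were also called in the same direction without the block. The blocked medians were -2.47 for photosynthesis, -1.15 for chlorophyll synthesis, 2.71 for the seed list and -2.34 for root markers.

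The fourth comparison asked how the genotypes differed without added glucose. Fewer genes differed on sorbitol than on glucose. CYP71A13 was at least 12.02-fold higher in anac060 (5.50 ± 0.45, adjusted p = 1.5e-04), PDF1.4 was 4.86 ± 0.29 higher (1.8e-05) and M17 3.097 ± 0.44 higher (0.0029). Besides ANAC060, the kinase gene ckl10 (-5.75 ± 0.10, above background on 2 of 3 anac060 arrays) and MRD1 (-5.58 ± 0.21) were lowest in anac060. In all, 3503 genes were called, 1498 higher and 2005 lower. Of these, 516 differed at least 2-fold, 292 higher and 224 lower.

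GSTU11 (5.34, at least 23.0-fold), the receptor-like gene RLP21 (4.48, at least 4.94-fold), the peroxidase gene PRX52 (3.76), and the transporter gene ABCB13 (3.63, at least 4.36-fold) were among the other large rises, with LTP3 (3.06), the cellulase gene CEL3 (2.89, at least 4.63-fold) and the nuclease gene ENDO2 (2.88). QQS, an orphan gene that affects starch (-4.01), LBD29 of lateral root formation (-2.66, 1 of 3 arrays), the nitrate transporter gene NRT1.5 (-2.35) and CYP71A27 (-2.29) were the next largest falls. NCED9 of ABA synthesis (-1.91), ST4B (-1.90) and NCED3 of ABA synthesis (-1.87) followed. The calls of NCED9 and NCED3 were lost without WT sorbitol array 2 (0.0783 and 0.0720) or 3 (0.0629 and 0.0667) or anac060 sorbitol array 1 (0.0690 and 0.0784) or 2 (0.0687 and 0.0653). With slide as a block the calls of GSTU11 (4.91, 0.177), ABCB13 (2.35, 0.197), CEL3 (4.19, 0.0715), QQS (-3.38, 0.0554), NCED9 (-2.26, 0.241), ST4B (-2.96, 0.0812) and NCED3 (-2.57, 0.138) were lost.

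Of 20 seed storage and maturation genes 8 were higher in anac060 and none lower (10 and 0 over the list alone), with SESA1 at 2.18, SESA5 at 2.04 and SESA2 at 1.88 (median 1.15, camera adjusted p = 2.2e-05; adjusted p = 0.636 with an estimated correlation). SESA1 was not called without anac060 sorbitol array 2 (0.0502) and SESA2 without WT sorbitol array 2 (0.0534) or 3 (0.0681) or anac060 sorbitol array 2 (0.0672). Anthocyanin genes were higher, 9 of 31 with 1 lower (11 and 2 over the list alone), with MYB111 at 1.14 and MYBL2, which represses the pathway, at 1.103 (median 0.26, adjusted p = 1.7e-04; adjusted p = 0.507 with an estimated correlation). MYB111 was not called without WT sorbitol array 2 (0.0614) or anac060 sorbitol array 1 (0.0511). Sugar sensing, transport and starch genes were higher, 4 of 25 with none lower, with GPT2 at 1.69 (median 0.18, adjusted p = 0.0044; adjusted p = 0.507 with an estimated correlation). These 3 lists were also called with slide as a block, at 2.64, 0.30 and 0.23, whereas GPT2 alone was not (1.94, adjusted p = 0.0614). The block takes the step between slides 1 and 2 from WT glucose array 1 against WT glucose arrays 2 and 3. That array stood apart in the seed list (0.55 against -0.61 and -0.89), so the rise of the seed median from 1.15 to 2.64 with the block comes mainly from it. The blocked seed call is therefore no separate support. With slide as a block MYB111 (1.51), MYBL2 (0.82), GUN5 (0.47), NIA1 (0.93), NIA2 (0.78), HAI3 (-1.15), ABI2 (-1.12), LHCB2.1 (0.60) and LHCB4.3 (0.62) kept their direction but were not called singly on sorbitol (adjusted p from 0.0632 to 0.397).

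The next 4 list calls on sorbitol were lost with slide as a block, which raised the median SE of a gene from 0.108 to 0.196. Chlorophyll synthesis genes were higher, 6 of 18 with 2 lower (11 and 2 over the list alone), with GUN5 at 0.72 but PORA at -1.27 (-0.62 by another probe) and PORB at -0.49 (-0.45 to -0.06 by its other probes) (median 0.34, adjusted p = 9.6e-04; adjusted p = 0.659 with an estimated correlation; 0.13 and 0.387 with slide as a block). Nitrate genes were higher, 5 of 9 with 1 lower (6 and 1 over the list alone), with NIA1 at 0.94 and NIA2 at 0.77 (0.38 and 1.39 by its other probes; list median 0.40, adjusted p = 0.0137; adjusted p = 0.507 with an estimated correlation; 0.20 and 0.0955 with slide as a block; 0.0606 with only the groups compared). ABA signalling genes were lower, 8 of 30 with none higher (14 and 3 over the list alone), with HAI3 at -1.67 and ABI2 at -0.90 (median -0.30, adjusted p = 0.0408; adjusted p = 0.650 with an estimated correlation; -0.26 and 0.206 with slide as a block). The ABA signalling call was also lost under normexp (0.181) and without WT sorbitol array 2 (0.0709) or 3 (0.0560), anac060 sorbitol array 1 (0.0552) or 3 (0.0613) or anac060 glucose array 1 (0.0548) or 2 (0.0898). It was 0.113 with only the groups compared and ran from 0.00267 to 0.206 over all settings with the preset correlation. HAI3 was not called without WT sorbitol array 2 (0.0576) or anac060 sorbitol array 1 (0.0595) or 2 (0.0565), and ABI2 without WT sorbitol array 2 (0.0896) or 3 (0.0731) or anac060 sorbitol array 1 (0.0847). Photosynthesis genes had a median of 0.07 with 2 of 55 higher, LHCB2.1 (0.91; 0.36 by its other probe) and LHCB4.3 (0.90), and none lower (adjusted p = 0.0137; adjusted p = 0.878 with an estimated correlation). The sign turned to -0.19 with slide as a block (adjusted p = 0.0837), and the call was lost without WT sorbitol array 3 (0.02, 0.209) or anac060 sorbitol array 1 (0.02, 0.0878) or 2 (0.02, 0.147).

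Other lists were not called by camera on sorbitol. ABA and dehydration induced genes numbered 2 higher and 5 lower (2 and 11 over the list alone; -0.46, 0.143; called without WT sorbitol array 1, -0.61, 0.0179), and ABA synthesis genes 3 and 3 (median 0.08 with a camera direction of up, mean -0.04, 0.618). Lipid mobilisation genes numbered 2 and 0 (1 and 0 over the list alone; 0.00, 0.618), and sugar starvation genes 3 and 1 (median -0.06 against a camera direction of up, 0.550). Jasmonate genes numbered 1 and 1 (-0.21, 0.882; -0.89 and 0.0471 with slide as a block) and salicylate and camalexin genes 2 and 1 (median -0.24 and mean 0.40, 0.991). Cell cycle genes numbered 0 and 0 (0.07, 0.177; 0.13 and 0.0269 without WT sorbitol array 3), and expansin genes 1 and 4 (0.06, camera direction down, 0.991). Root markers numbered 0 and 1 (-0.19, 0.434), guard cell markers 0 and 2 (-0.08, 0.618) and the membrane-tethered NAC genes 0 and 1, ANAC060 itself. LHCB1.1 (-0.10), RBCS1A (-0.24), PAP1 (-0.56; -0.55 and called under normexp), ABI3 (0.07), ABI4 (0.41), ABI5 (0.29), EM6 (0.25), RAB18 (0.46; called with only the groups compared, 0.0390), RD29B (0.27), HXK1 (0.05), APL3 (0.24) and TT4 (0.38) were not called, nor was ASN1.

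The count on sorbitol was the least stable. It fell to 1079 without WT sorbitol array 2, 1738 without WT sorbitol array 3, 1093 without anac060 sorbitol array 1 and 1384 without anac060 sorbitol array 2. A model blocked on slide called 211 genes, 148 higher and 63 lower, 179 of which were also called in the same direction without the block. Of the called genes 42.8% were higher here, 29.6% under normexp and 55.6% under median centring.

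**Figure D3:**
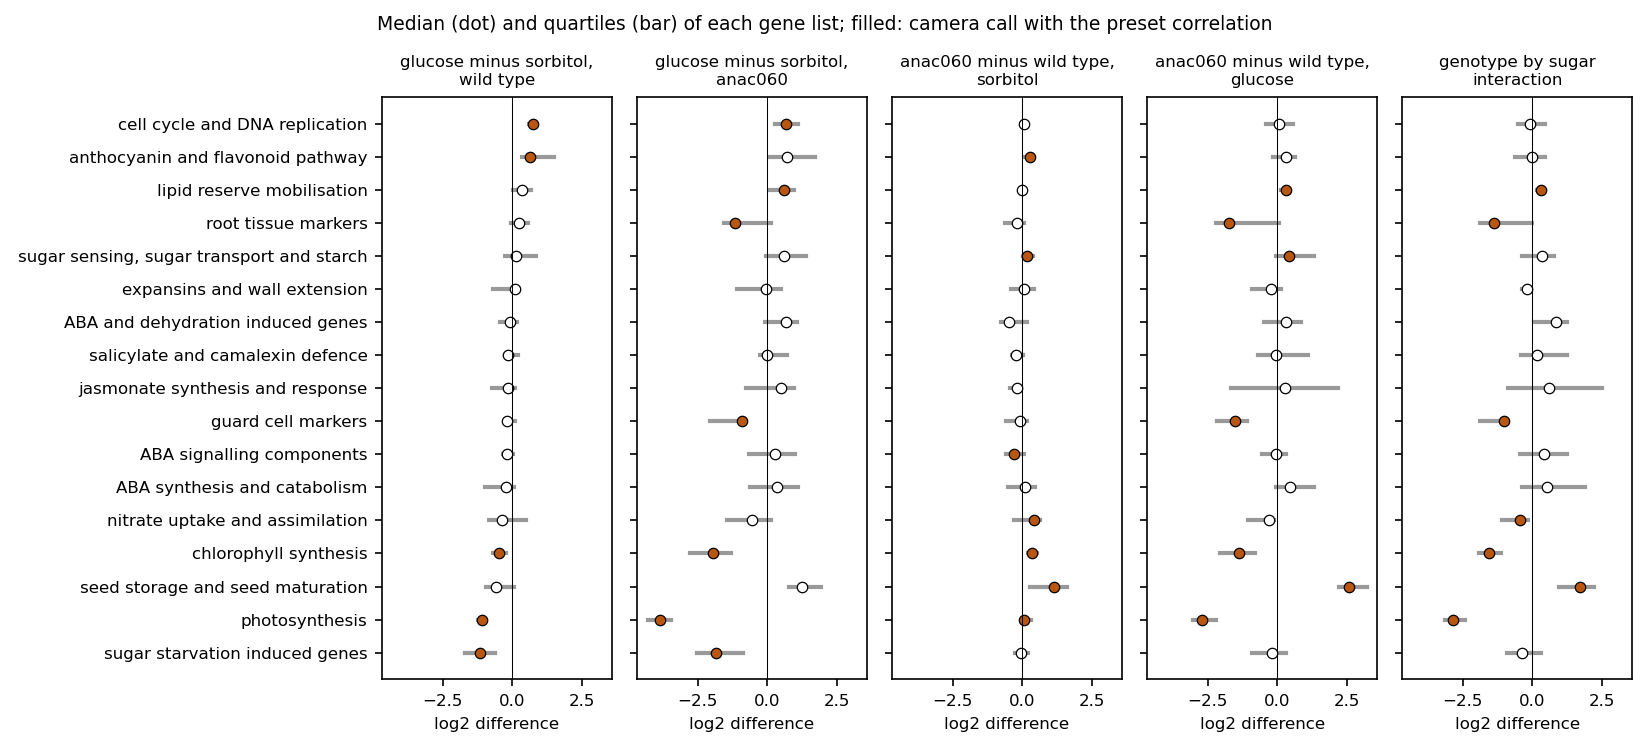
Median (dot) and quartiles (bar) of the log2 differences of 17 gene lists in the 5 comparisons; filled dots passed camera with the preset correlation, and no list passed with an estimated one. The photosynthesis median was -1.09, -3.84, 0.07 (-0.19 with slide as a block), -2.69 and -2.85 from left to right.

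The interaction asked whether the effect of glucose differed between the genotypes, as the difference of the mutant effect minus the wild type effect. Photosynthesis genes fell further in anac060 by the list test with the preset correlation, though not with an estimated one (adjusted p = 0.507), with an interaction of -2.93 ± 0.37 for LHCB1.1 (adjusted p = 2.4e-04) and -5.15 ± 0.46 for LHCB2.3 (4.5e-05). ABI3 (2.22 ± 0.33, adjusted p = 5.2e-04) and ABI4 (1.55 ± 0.24, 6.7e-04) moved upward more in anac060. A total of 11093 genes were called, 5987 with a positive and 5106 with a negative interaction (1421 and 2597 at 2-fold or more). Among them were 4100 genes that glucose changed in the same direction in both genotypes, 3883 of them more in anac060 and 217 more in the wild type, and 847 that it changed in opposite directions.

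Positive interactions were largest for ENODL1 (5.35), BGLU27 (5.28), GLIP1 (5.16), CORI3 (5.10; 2.29 and 5.26 by its other probes), SAG13 (4.79), the jasmonate repressor gene JAZ8 (4.77) and CYP71A12 (4.39), and then for the mitochondrial phosphate carrier gene PHT3;2 (4.27), the oligopeptide transporter gene OPT5 (4.18) and ABCC9 (4.11). Negative interactions were largest for XTH6 (-6.00), BGLU35 (-5.55), SAUR63 (-5.53), LHCB2.3, RGF9 (-4.95), the brassinosteroid response gene BEE3 (-4.91), SAUR20 (-4.88), CA1 (-4.85), PELPK1 (-4.84) and PPT2 (-4.81). For 16 of these 20 genes at least 1 group was not above background on every array, so the fitted interaction is not exact in size. OPT5, LHCB2.3, CA1 and PELPK1 were above background on all 12. Other probes gave -4.07 and -3.75 for PELPK1, -5.73 for LHCB2.3 and -5.90 to -4.87 for CA1. In anac060 glucose array 1, BGLU27, GLIP1 and SAG13 stood above the other 2 arrays, and without it their interactions were 4.11, 3.52 and 4.04. JAZ8 was not called without WT sorbitol array 1 (0.0650) or 2 (0.0688), WT glucose array 1 (0.0543) or 2 (0.0564), anac060 sorbitol array 1 (0.0646) or 2 (0.0589) or anac060 glucose array 3 (0.0583). CYP71A12 was not called without WT sorbitol array 3 (0.0562), WT glucose array 2 (0.0539) or 3 (0.0583) or anac060 sorbitol array 1 (0.0554) or 2 (0.0546). With slide as a block BGLU27 (5.16, 0.0632), GLIP1 (5.37, 0.131), JAZ8 (2.64, 0.330), CYP71A12 (3.70, 0.265) and PHT3;2 (3.35, 0.0745) were not called, nor was GLIP1 under normexp (2.54, 0.0543).

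All 55 photosynthesis genes had a negative interaction (median -2.85, camera adjusted p = 1.2e-30; adjusted p = 0.507 with an estimated correlation), as did 17 of 18 chlorophyll synthesis genes (median -1.55, adjusted p = 7.2e-11; adjusted p = 0.507 with an estimated correlation), with GUN5 at -3.03. Root markers had 12 negative and 1 positive of 20 (13 and 1 over the list alone; median -1.38, adjusted p = 0.0137; adjusted p = 0.636 with an estimated correlation), with SKOR at -1.89, and nitrate genes 5 and 0 of 9 (median -0.46, adjusted p = 0.0137; adjusted p = 0.507 with an estimated correlation), with GLU1 at -2.33 and GLN2 at -2.09. These 4 lists were also called with slide as a block, at -2.32, -1.24, -1.44 and -0.33.

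The next 3 lists were not called with slide as a block. Seed storage and maturation genes had 11 positive and 0 negative of 20, with CRA1 at 2.74 and PER1 at 2.60 (median 1.70, adjusted p = 0.0060; adjusted p = 0.679 with an estimated correlation; 0.49 and 0.0837 with slide as a block). All 5 guard cell markers were negative (median -1.02, adjusted p = 0.0157; adjusted p = 0.636 with an estimated correlation; 0.0560 with slide as a block and 0.0831 under normexp). Lipid mobilisation genes had 6 positive and 0 negative (median 0.31, adjusted p = 0.0417; adjusted p = 0.652 with an estimated correlation; 0.25 and 0.104 with slide as a block; 0.135 under normexp). The lipid call was also lost without WT sorbitol array 2 (0.0763), WT glucose array 3 (0.0535), anac060 sorbitol array 1 (0.0522) or anac060 glucose array 1 (0.0677) or 3 (0.0580) and with the most detected probe per gene (0.0581). Across all settings with the preset correlation its adjusted p ran from 0.0176 to 0.135.

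The other lists were not called by camera. ABA signalling genes numbered 15 positive and 9 negative (0.42, 0.391), ABA and dehydration induced genes 12 and 2 (0.83, 0.115; 0.0316 without WT sorbitol array 1 and 0.0429 without WT glucose array 1) and ABA synthesis genes 8 and 4 (0.54, 0.520). Anthocyanin genes numbered 7 and 9 (-0.03, 0.720), sugar sensing and starch genes 10 and 5 (0.36, 0.327), and sugar starvation genes 4 and 6 (-0.36, 0.181). Jasmonate genes numbered 2 and 3 (0.60, 0.885), salicylate genes 2 and 3 (median 0.15 against a camera direction of down, 0.975), cell cycle genes 5 and 6 (-0.07, 0.885), expansin genes 2 and 2 (-0.19, 0.391) and the membrane-tethered NAC genes 2 and 0. The last 2 were ANAC089 and ANAC060 itself, whose probe was well above background on 0 of 3 sorbitol and 1 of 3 glucose arrays of anac060. The effect of glucose on ASN1 (0.59), GPT2 (0.54), PAP1 (-0.58), HXK1 (0.15) and TT4 (0.22) was not called as different between the genotypes. ABI5 (1.60), EM6 (1.87), APL3 (1.22), RAB18 (1.42), RD29B (1.00), RBCS1A (-0.51) and ANAC060 (0.79) were called, but each call was lost with slide as a block, at 0.92, 0.91, 0.74, 0.57, 0.13, -0.23 and 0.54, and that of ANAC060 also under normexp (0.41, 0.0617). RBCS1A, at -1.66 to -0.59 by its other probes, was also not called without WT sorbitol array 1 (0.0560) or 3 (0.0595), WT glucose array 2 (0.0514) or 3 (0.0605), anac060 sorbitol array 1 (0.0610) or 2 (0.0623) or anac060 glucose array 3 (0.0546). RD29B lost its call without WT sorbitol array 2 (0.0898) or 3 (0.0876), WT glucose array 2 (0.0752) or 3 (0.0563), anac060 sorbitol array 1 (0.0929) or 2 (0.0874) or anac060 glucose array 1 (0.0833), 2 (0.0716) or 3 (0.0602) and under median centring (0.0516) or with no filter on dim probes (0.0638). A model blocked on slide called 3997 genes, 3941 of which were also called in the same direction without the block.

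**Figure D4:**
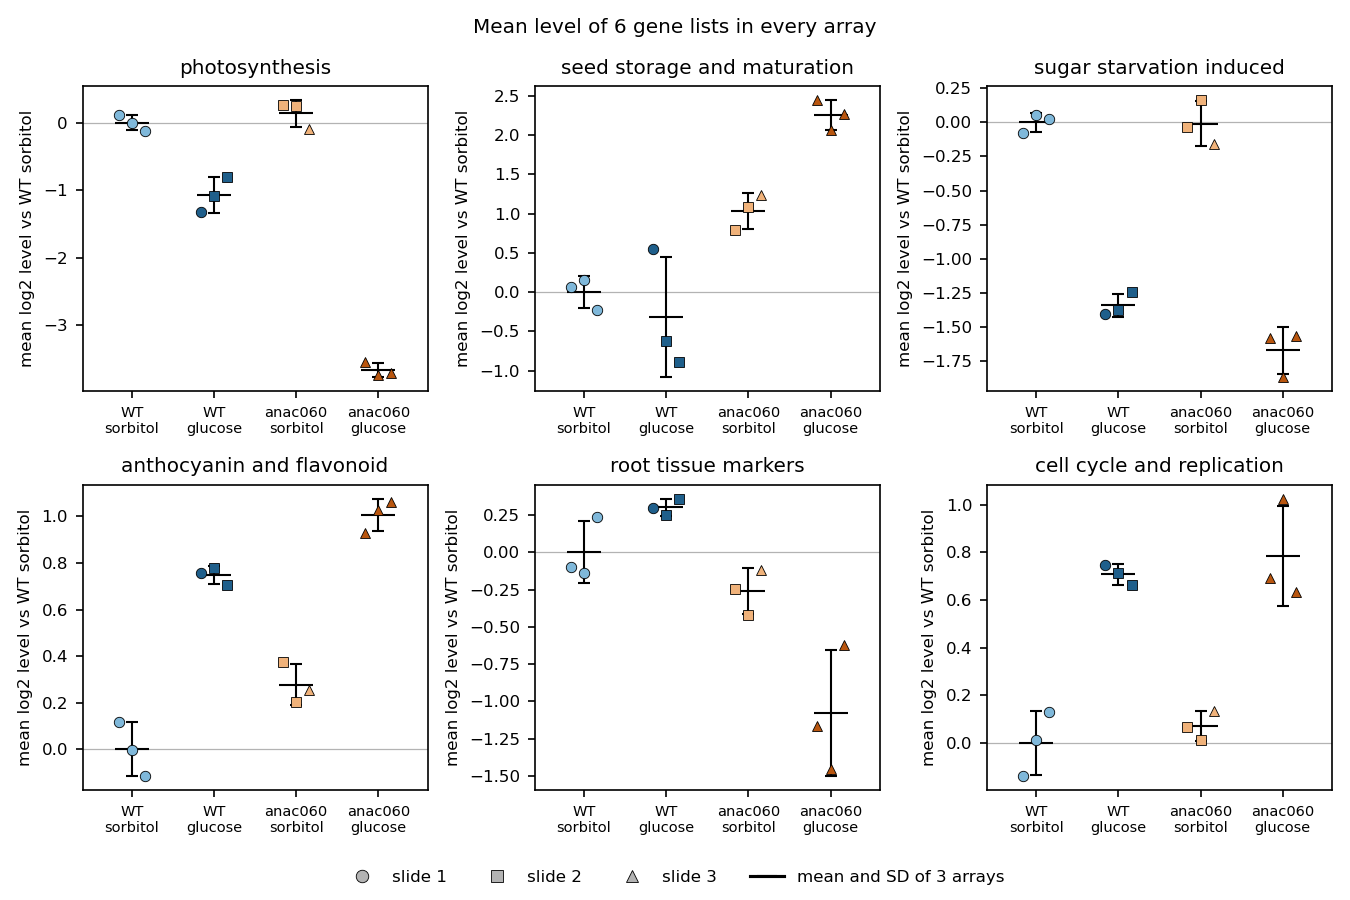
Mean log2 level of 6 gene lists in every array relative to the mean of the wild type on sorbitol; points are single arrays, shapes give the slide, and bars are the mean and SD of 3 arrays. In the seed list WT glucose array 1 stood at 0.55 and the 3 anac060 glucose arrays between 2.07 and 2.44.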

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

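The tests of array scaling, slide, root tissue, seedling stage and ungerminated seeds were chosen only after the results they weigh had been seen.

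The results in this part were picked because the interaction test called a difference between the effects of glucose in the 2 genotypes, or because probes outside the comparisons carried signal. The interaction called 11093 genes. Of the 100 pairs of splits of the arrays of each genotype, only the real one (1) called as many, and the highest other called 9361. Most of these splits could not have called many genes, because regrouping the anac060 arrays turns its large effect of glucose into spread: the 9 that regrouped anac060 arrays only called 1 to 163 and the 81 that regrouped both called 0. The 9 splits that regrouped wild type arrays and kept the sugars of anac060 called 7028 to 9361, so a structure of the samples, the large effect of glucose in anac060, yields most of such a count. Together with the real one these make 10, too few for a share under 0.05, and the share of the 100 is not read further. All 10 splits of each genotype were paired, in place of the random draw first planned.

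Gene lists picked by the interaction test, each called with the preset correlation and none with an estimated one, were photosynthesis (-2.85), chlorophyll synthesis (-1.55), nitrate (-0.461), root markers (-1.38), guard cell markers (-1.02), the seed list (1.705) and lipid mobilisation (0.308). Single genes picked by it with a positive value were ENODL1 (5.35), BGLU27 (5.28), GLIP1 (5.16), CORI3 (5.10), SAG13 (4.79), JAZ8 (4.77), CYP71A12 (4.39), PHT3;2 (4.27), OPT5 (4.185) and ABCC9 (4.11), and among the fixed genes ABI3 (2.22), EM6 (1.87), ABI5 (1.60), ABI4 (1.55), RAB18 (1.42), APL3 (1.22), RD29B (0.999) and ANAC060 (0.785, its probe near background in anac060). Those with a negative value were XTH6 (-6.00), BGLU35 (-5.55), SAUR63 (-5.53), LHCB2.3 (-5.15), RGF9 (-4.95), BEE3 (-4.91), SAUR20 (-4.88), CA1 (-4.85), PELPK1 (-4.84), PPT2 (-4.81), LHCB1.1 (-2.93) and RBCS1A (-0.511).

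Probes paired with no locus were picked because they carried signal outside the comparisons: of 3143 tested, 1329 were called for glucose in the wild type, 1889 for glucose in anac060, 1568 for genotype on glucose, 493 for genotype on sorbitol and 1300 for the interaction.

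The deeper fall of photosynthesis genes on glucose in anac060 was weighed first. Array scaling as its cause is argued against by an interaction median that reached at most -2.839 under the 4 other scalings, and the slide by a median of -2.32 with slide as a block. A larger share of root tissue is argued against by root markers that were lower in anac060 on glucose, not higher (-1.742). A hold at an early seedling stage would need seed genes to rise more on glucose in anac060, and they did (interaction median 1.705), but with slide as a block, where the wild type effect rests on glucose array 1 alone, which stood apart in this list, the median was 0.49 and not called, so this reading stays a hypothesis. The seed list was also higher in anac060 on sorbitol, where no fall of the photosynthesis list was called. The photosynthesis median there was 0.07, and -0.19 with slide as a block. A raised seed list thus did not always go with lower photosynthesis genes. A direct action of ANAC060 on photosynthesis genes was not tested.

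The second pattern was the set of genotype differences on sorbitol, 3503 genes. Slide alone is argued against as the cause of their sizes, since the lower quartile of the ratio of blocked to unblocked differences was 0.8834, but the block left 211 calls because the median SE rose from 0.108 to 0.196, so how many genes differ stays open. The block takes this slide step from WT glucose array 1 against arrays 2 and 3 alone, so the argument holds only as far as that step stands for the slides. A stretch of chromosome that differs between the lines was tested only as ANAC060 and the 50 tested genes on either side. It held 1.172% of the 2-fold calls (6 of 512 placed). A stretch with so few genes could not have held most of 512 calls, even with every gene in it called. That share therefore cannot decide whether such a stretch differs, and no conclusion is drawn from it. Of its genes 5.94% were called, against 2.45% elsewhere (Fisher exact p = 0.0389, and 0.101 without ANAC060). A longer stretch, or effects of such a stretch on genes elsewhere, was not tested. Stretches of another strain elsewhere cannot be told apart from chance clusters or from clusters of related neighbours. The fullest window of that size held 10 calls, equal to the 95th percentile over 1000 shuffles (10) and above their median (9). Windows on chromosome 2 (with UGT73C1 and UGT73C6) and on chromosome 3 (with QQS, NIT1, NIT2 and ANAC060 itself) reached it. The chromosome 3 window does not lie elsewhere. It overlaps the stretch tested around ANAC060 and counts ANAC060 among its 10 calls, so it bears on a stretch around that gene as well. The shuffles treated neighbouring genes as independent, whereas neighbours of one family, such as UGT73C1 (1.95) and UGT73C6 (2.19), can change together or share signal. The 10 splits of these 6 arrays are too few for a share under 0.05; the real one (1 of 10) called 3503 and the highest other 105.

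The third pattern was the higher level of seed maturation genes in anac060 on glucose. Scaling is argued against by a list median of at least 2.445 under the 4 other scalings. With slide as a block the median was 2.706. That value leaves out WT glucose array 1, which stood apart in this list (0.55 against -0.61 and -0.89 in arrays 2 and 3). It takes the slide step from anac060 sorbitol array 3 against arrays 1 and 2 alone. It therefore argues against the slide only as far as that step stands for the slides. Seeds that had not germinated, or seed coats, carried along in the anac060 samples stay open: lipid mobilisation genes, which seeds use after germination, were higher in anac060 by a median of only 0.3189, and the bound of this test was made stricter after the value was known. Seed genes were also higher on sorbitol (median 1.15, 8 of 20 called, the list only with the preset correlation and at 0.636 with an estimated one), so a slower loss of the seed programme in anac060 on either sugar could give the same values, as could a larger share of such seeds.

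For the other 3 comparisons too the 10 splits of 6 arrays are too few for a share under 0.05, and only the real split (1 of 10) called as many genes. The real and the highest other counts were 10643 and 2 for glucose in the wild type, 15633 and 0 for glucose in anac060, and 13932 and 0 for genotype on glucose. Here and on sorbitol, every other split mixes the arrays of both groups and turns their difference into spread. Low counts there would follow from any difference between the groups, whatever its cause, so the gap is not read further.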

How the results depend on the processing

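The fits on slide 1 or slide 3 alone were chosen after seeing the data, and the other settings beforehand. Direction and side of the threshold, or a count within 1.5 times, were kept by all 5 counts of calls, the count of called lists and the correlation of the glucose effects under normexp, quantile normalization, median centring, the authors' value table, both other filters, outlier spots kept, both other choices of probe, limma with trend and robust moderation and the replicate block, and by the 6 of these results that can be had with only the groups compared. ANAC060 stayed called lower in anac060 under every setting, at -2.40 (sorbitol) and -1.99 (glucose) under normexp, -3.92 and -3.20 in the value table and -4.28 and -3.74 with slide as a block. Its probe was near background in anac060, which makes the size depend on the background.

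With slide as a block 7694 genes (13932 without) were called for genotype on glucose, 211 (3503) for genotype on sorbitol and 3997 (11093) for the interaction, and the correlation of the glucose effects was 0.663 (0.565). Among genes called without the block, the median ratio of blocked to unblocked differences was 1.00, 1.09 and 0.852, and the median SE rose from 0.108 to 0.196 for both genotype effects and from 0.152 to 0.209 for the interaction. Fewer calls thus came with larger errors rather than smaller differences on either sugar, while the interaction was also somewhat smaller. The photosynthesis list on sorbitol changed sign (-0.19 with slide as a block), as did RBCS1A for glucose in the wild type under quantile normalization (0.15) and in the value table (0.045); the cause was not tested.

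By construction, stricter thresholds called fewer genes. At least 2-fold left 1947 for glucose in the wild type, 5905 for glucose in anac060, 4372 and 516 for genotype on glucose and sorbitol and 4018 for the interaction. An adjusted p under 0.01 left 804 for genotype on sorbitol and 7330 for the interaction, and the other 3 counts stayed within 1.5 times. Fewer arrays gave 5822 calls for glucose in the wild type on slide 1 alone and 8213 for glucose in anac060 on slide 3 alone, where the lone array of a group is assumed to vary like the other group. With an estimated correlation camera called 0 of the 85 list tests, against 33 with the preset one and 46 by fry.

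Leaving out 1 array gave ranges of 8727 to 11502 calls for glucose in the wild type, 14609 to 15640 for glucose in anac060, 12292 to 13998 and 1079 to 4697 for genotype on glucose and sorbitol, 9312 to 11312 for the interaction and 28 to 38 called lists. The ANAC060 difference ran from -4.18 to -3.86 on glucose and -4.93 to -4.73 on sorbitol, and the correlation from 0.505 to 0.603. Of the list values under these settings 989 were on the same side, 20 lost and 11 gained a call, and of the values of named genes 5739 were on the same side, 194 lost and 19 gained a call. With slide as a block 10 list values lost and 2 gained a call, beside the photosynthesis list on sorbitol, which lost its call as its sign turned, and 113 values of named genes lost and 1 gained one.

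With array number as a replicate block 10449, 15555, 13694, 3102 and 10799 genes were called in the order of the comparisons. The numbers did not pair the arrays: 3 of 18 pairs of the same number had r over 0.1 (-0.22 to 0.27), and 3 of 12 arrays correlated best with their own number.

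Signal over background limits fold sizes wherever a group was not detected, and normexp, whose offset compresses dim signal, changed the balance of calls: 49.3% of calls for glucose in the wild type were higher, against 60.4% without it. The median of all genes moved with the sugar (0.0692 in the wild type, 0.167 in anac060), so the balance of rises and falls depends on the scaling.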

Other observations

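The 3 gene lists in this part were written after the largest changes had been seen, and the tests were run only on members whose values had not been looked at. The slide block was added to them later.

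Glucose raised genes of phosphate starvation in the wild type. PS2, which encodes a pyrophosphatase, rose by 3.00 ± 0.25, the phosphate sensor gene SPX1 by 2.28 ± 0.17 and the acid phosphatase gene PAP17 by 1.83 ± 0.14. MGD2 (1.39), PLDP2 (1.31) and SQD1 (1.16) of the exchange of phospholipids for galactolipids and sulfolipids rose too, all on probes above background on all 12 arrays. This was tested as the hypothesis that 6% glucose brings a phosphate starvation response, after MGDC, SPX3 and PEPC1 had been seen to rise. Of 11 members not seen before 8 rose and 0 fell (median 1.156, camera adjusted p = 0.00135 and fry 2.4e-05; 0.520 for camera with an estimated correlation). The slide block left 6 higher and 0 lower (0.918, camera 0.00149). In anac060 6 rose and 3 fell (median 0.369, camera adjusted p = 0.517, fry 7.0e-04), with PS2 at 3.72 and SPX1 at 1.15 but PHO1;H1 at -0.83. Compared with the wild type, these genes were lower in anac060 on glucose, 9 of 11 with 0 higher (median -0.820, camera adjusted p = 0.00278), and on sorbitol, 6 of 11 with 0 higher (-0.579, 0.00711), but neither call held with an estimated correlation (0.520 for both). Blocked on slide, both differences stayed called, on glucose with 10 of 11 lower (-0.883, 4.2e-04) and on sorbitol with 1 of 11 called lower singly (-0.618, 1.5e-04). The interaction (-0.508) was not called by camera (0.0626) but was by fry (0.0098), though not with slide as a block (0.160). The values are consistent with a phosphate starvation response on glucose (median 1.156), with a lower level of these genes in anac060 on glucose, and phosphate itself was not measured.

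Lists of sulfur deficiency and heat shock genes gave weaker results. LSU2 rose by 2.51 ± 0.36 in the wild type and 2.60 ± 0.36 in anac060, APR1 of sulfate reduction by 1.60 and 1.77, and the vacuolar sulfate exporter gene SULTR4;2 by 1.14 and 1.64, whereas the uptake gene SULTR1;1 had a log2 difference of -2.82 in anac060 (above background on 1 of 3 glucose arrays). For the hypothesis of a sulfur deficiency response on glucose, 5 of 8 unseen members rose and 1 fell in the wild type (median 0.7169, fry adjusted p = 3.4e-04, camera adjusted p = 0.0626) and 5 rose and 1 fell in anac060 (0.781, fry 1.4e-04, camera 0.233). Blocked on slide, 3 rose and 0 fell in the wild type (0.513) and 6 rose and 1 fell in anac060 (1.02). The list thus passed fry and not camera. For the hypothesis of a weaker heat shock response on glucose, 4 of 7 unseen members fell and 1 rose in the wild type (median -1.309, fry adjusted p = 0.00587, camera adjusted p = 0.0626; -1.80, 3 lower and 1 higher, with slide as a block). HSP101 was at -1.52 and HSP70 at -1.01, and HSP18.2 rose by 1.00. In anac060 the median was 0.095 with 1 higher and 2 lower, and the interaction had a median of 1.23 (camera adjusted p = 0.267, fry 0.0450; fry 0.134 with slide as a block). On sorbitol the list was lower in anac060 by fry (median -0.865, adjusted p = 0.0371; 0.189 with slide as a block) and not by camera (0.0626). None of these camera results passed with an estimated correlation.

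On sorbitol 5 neighbours of ANAC060 were called at 2-fold or more: the nitrilase genes NIT2 (1.29, and 1.59 on glucose) and NIT1 (1.01 and 0.20), AT3G44450 (1.29 and 0.76), AT3G43940 (-1.14 but 0.81 on glucose) and AT3G43550 (-1.10 but 0.52).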
